A study of Mus musculus with 2 samples.

How the data were processed

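DNase-seq was carried out on kidney of male B6CASTF1/J mice aged 36 days, with 2 libraries in 1 group. The labels call them biological replicates 1 and 2 and number the animals 5 and 6, while giving both the same donor identifier. Only the library of replicate 1 has its instruments in the labels, a HiSeq 4000 and a NovaSeq 6000, so depth, instrument and animal cannot be separated.

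Per the labels, the files are on assembly mm10, and per the deposited file lists each was derived from 1 library's alignments, so peaks and footprints were called per library. The aligner, the caller, their versions and thresholds are not given in the sources used here. The deposited peak files give a signal value per peak, made by the authors; the signal lies on a grid of whole steps, of 0.00369 in replicate 1 and 0.00739 in replicate 2 (100% of values, within 0.05 of a step), which would correspond to 271 M and 135 M cleavages if a step is a single cleavage scaled by depth. That depth is an inference from the grid. The deposited false discovery rate (q-value) files list runs of bases with a rate of at most 0.05, 71.8 Mb in replicate 1 and 59.1 Mb in replicate 2. The authors' footprint files carry a single p-value column that is constant at 0.01, so footprints could not be ranked. Each library had 2 peak files of the same peak width (median 180 bp). In the smaller one every peak held a base with a rate of at most 0.001, and in the larger one nearly all reached 0.05 (235067 and 194505 peaks). The smaller set was the main one.

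Peaks on chromosomes 1 to 19, X and Y were used. Peaks of a library that overlapped each other were joined and kept the higher signal, which joined 863 and 443. Coordinates were checked against the GRCm38 reference and its GENCODE annotation, and 0 intervals ran beyond a chromosome end. The sequence is that of C57BL/6J, although the animals carry a CAST/EiJ genome too, and effects of strain variants on mapping were not analysed here. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

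Regions were shared if they overlapped by at least 1 bp, and the background was 100 seeded random placements on the same chromosome, outside assembly gaps. Classes were assigned by the midpoint: promoter (within 500 bp of a transcription start), exon, intron or intergenic. A region was distal if it overlapped no window of 500 bp around a start, and the locus was the gene body and 10 kb on either side. For each of 23 gene lists the median distal density and the share of genes with a promoter region were set against 10000 random lists of protein-coding genes of the same size, matched on class of locus length (10 classes). The test was a two-sided permutation with Benjamini-Hochberg adjustment over lists, called if the adjusted p was under 0.05 in both libraries. It describes these libraries, since genes are not independent replicates. The lists were proximal tubule, thick ascending limb, distal convoluted tubule, principal cell, intercalated cell, podocyte, endothelial, stroma with smooth muscle and renin cell, immune, nephron progenitor, male-biased and female-biased tubule genes, hepatocyte, neuron, striated muscle, germ cell, erythroid, urothelium, adrenal cortex, adipocyte, housekeeping, kidney transcription factors and transcription factors of other lineages.

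For motifs, footprints inside regions were widened by 5 bp and compared with windows of the same length in the same region outside any footprint. Footprints without such a control window were left out, so 347504 of 437866 in replicate 1 and 280412 of 310004 in replicate 2 were used. Matches to 26 consensus sequences on either strand were counted, folds were computed after adding 0.5 to both counts, and Fisher's exact test was two-sided per library. The test ignores that each control window comes from the region of its footprint and that control windows of a region can overlap. The libraries also share most regions, so a call in both is not independent replication. Where no control matched, folds are lower bounds against a floor of 3 counts. With 1 to 3 matches the ratio is given with a 95% exact interval. These cover counting error only.

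The gene lists, the motifs, the tests of lists, regions and footprints and the rule for named genes were fixed before the data were examined. The joining of overlapping peaks, the comparison of distal with promoter footprints, the footprints per quartile of region strength, the use of the false discovery rate files and the signal ratios between the libraries were chosen afterwards. The rule names the 2 densest and the least dense gene of each list, the 10 protein-coding loci with the most distal regions, the 10 shared regions with the best lower rank, the 5 strongest single-library regions of each library, and the 5 most and 3 least enriched motifs. Other genes and motifs were chosen after their values were seen: Alb, Ttr and Cyp7a1, and the remaining motifs named beyond the extremes. Results for some genes and motifs among those tested are not reported here. Alternatives were the larger peak set, the stronger regions of each library, equal numbers of regions, reciprocal overlap of 50%, a promoter window of 1000 bp, loci of the gene body alone or with 50 kb, autosomes only, leaving out each library, footprints not widened and control windows beside the footprint. Thinning windows to equal GC content was added after the data were seen. An analysis limited to the stronger footprints could not be run because of the constant column.

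The test of distal density, the motif search and the shift in signal of gene lists were tested on simulated data; the other procedures were not. With the distal density of 25 lists of genes raised 2-fold, 3-fold or 4-fold, 2, 9 and 19 lists were called, and 0 of 90 unchanged lists at each fold, over 21938 genes. This simulation first used only the 2-fold change and was extended after its low recovery was seen. Moderate differences of small lists can therefore be missed. In random sequence with CTCF sites planted in 800 windows, 805 matches were found against 4 in controls, and 0 of 25 other motifs were called. For the shift in signal of gene lists, 5 of 5 lists moved by 0.5 on the log2 scale were called and 0 of 18 unchanged ones, over 18086 genes. This simulation shuffled the ratios over all regions, which removes any likeness between neighbouring regions of a locus. It therefore does not give the rate of recovery or of false calls in the real data.

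For shared regions, the ratio of the signals of the libraries was taken on the log2 scale and centred on the median region. The median over classes of GC content and of strength (20 each) was then subtracted, and gene lists were compared with matched random lists as before. Regions with a motif were compared with random draws of as many shared regions (10000 draws, or 2000 for motifs with 5000 regions or more). Because the signals are each library's own, this was repeated, after the first values were seen, on the percentile of a region among the shared regions of its library.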

Results

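DNase-seq maps accessible chromatin: the enzyme DNase I cleaves DNA that is not wrapped tightly around nucleosomes, and the cleavage sites are sequenced. The series held kidney from male B6CASTF1/J mice, hybrids of the C57BL/6J and CAST/EiJ strains, aged 36 days. It had 1 group with 2 libraries, which the labels number as biological replicates 1 and 2 and assign to animals 5 and 6. No second condition was present, so the questions were which chromatin was accessible in this tissue, which gene groups and sequence motifs it carried, and how far the libraries resembled each other. The smaller deposited peak set held 155040 peaks in replicate 1 and 132649 in replicate 2. If each step of the signal values is a single cleavage scaled by depth, the libraries held 271 M and 135 M cleavages. All coordinates are on mm10 (GRCm38).

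The chromatin region with the highest signal in both libraries lay in an intron of Mid1 on chromosome X (169998241 to 169998400), with a signal of 86.9 ± 29.9 (SD, n = 2). It had 108 in replicate 1 and 65.7 in replicate 2, and mapping or copy number at this position was not examined. The next 9 were at promoters. They were those of Dynlt1b, a dynein light chain gene (chromosome 17, 6430021 to 6430180; signal 71.1 ± 9.91), and of Hjurp, the chaperone of the centromeric histone (chromosome 1, 88277521 to 88277760; 57.9 ± 0.429). Sugct followed with 60.6 ± 6.22 (chromosome 13, 17694881 to 17695060) and Bahcc1 with 54.7 ± 3.35 (chromosome 11, 120232761 to 120232880). The promoter regions of Dnpep (53.0 ± 5.35), Ankhd1 (49.0 ± 1.59), the nuclear pore gene Nup107 (53.1 ± 7.63), Srl (48.9 ± 5.35) and Ctdsp2 (45.7 ± 0.482) completed the 10. After overlapping peaks were joined, replicate 1 had 154177 regions covering 28.03 Mb and replicate 2 had 132206 covering 23.7 Mb, a mean of 143192 ± 15536. Of the regions, 73.9% in replicate 1 and 86.2% in replicate 2 overlapped a region of the other library (mean 80.1% ± 8.72). Regions placed at random on the same chromosomes overlapped at 1.94% and 2.25% on average, and at no more than 2.02% and 2.35% in 100 placements. Across 113929 pairs of shared regions, the signal had a Spearman's rho of 0.857; regions are not independent replicates, so no p-value is given.

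Promoters were the most over-represented class of accessible chromatin in mouse kidney. They held 20.8% ± 0.745 of regions (SD, n = 2) against 2.53% of the genome, which is 8.25-fold. Exons held 6.36% ± 0.560 of regions and 3.51% of the genome, introns 41.6% ± 0.231 and 39.5%, and intergenic sequence 31.2% ± 0.0464 and 54.5%. Promoter regions were also stronger: their median signal was 2.72 in replicate 1 and 3.29 in replicate 2, against 0.800 and 1.00 for intergenic regions. Of 21938 protein-coding genes, 69.8% had an accessible promoter in replicate 1 and 67.04% in replicate 2, with 14606 genes (66.6%) in both, 6519 (29.7%) in neither and 813 (3.71%) in 1 library only. The X chromosome, present once in males, had a region density of 0.341 ± 0.00784 relative to autosomes, and the Y chromosome held 45 and 21 regions. The promoter share depended on the set of regions, and fell to 16.2% in the larger deposited peak set and rose to 30.9% among the stronger regions of each library.

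Genes of the proximal tubule, the nephron segment that reabsorbs most of the filtrate, were among those with the densest distal accessible chromatin. The median proximal tubule gene had 1.64 ± 0.370 distal regions per 10 kb of locus (SD, n = 2), and 20 of 25 genes lay above the median protein-coding gene in both libraries. Kidney transcription factor genes followed with 1.46 ± 0.133 (17 of 23 genes), endothelial genes with 1.35 ± 0.0858 (12 of 15) and genes of the thick ascending limb, which dilutes the urine, with 1.30 ± 0.275 (11 of 15). These 4 lists were denser than expected from 10000 random lists of genes matched on locus length in both libraries. The adjusted permutation p was 0.0023 in each library for proximal tubule and for kidney transcription factors, 0.0138 and 0.0092 for endothelial, and 0.0138 and 0.0414 for thick ascending limb. No list lay below its random lists in both libraries, at an adjusted or at an unadjusted p (0 of 23). Some lists could not have done so, because a density cannot fall under 0. The lower random bound was 0 in both libraries for germ cell, erythroid, urothelium, adrenal cortex, adipocyte and other-lineage transcription factor genes. It was 0 in replicate 2 for hepatocyte, immune, housekeeping and nephron progenitor genes. Only the remaining lists were therefore tested for a lower density.

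Among proximal tubule genes, Pdzk1, which encodes a scaffold of apical transporters (chromosome 3, 96829284 to 96870926), had 38 distal regions in replicate 1 and 16 in replicate 2. Slc34a1, the main phosphate transporter of this segment (chromosome 13, 55398187 to 55415592), had 15 and 7, whereas the lactate transporter gene Slc5a12 had 0 and 1. Emx2 (chromosome 19, 59458372 to 59465357) and Irx3 (chromosome 8, 91798525 to 91802067), transcription factor genes of kidney development, reached densities of 4.26 ± 1.31 and 3.82 ± 1.20 per 10 kb, and Hnf4g had 0.265 ± 0.125. In the endothelial list, Egfl7 had 4.68 ± 1.92 and Sox18 4.36 ± 0.324, against 0.270 ± 0.127 for Emcn, the gene of the surface protein endomucin. In the thick ascending limb list, Irx2 had 1.97 ± 0 and Irx1 1.74 ± 0.274, and the tight junction gene Cldn16 had 0.126 ± 0.178. The order of the lists depended on the setting: kidney transcription factors exceeded proximal tubule genes with the stronger regions, with autosomes only and with either other locus, and endothelial genes did so with either other locus. The call for thick ascending limb was lost when the locus was the gene body alone (density 0.769) or extended by 50 kb (0.887), and that for endothelial genes when only the stronger regions were used (0.588); these densities are on other scales than the main ones, so only the calls can be compared.

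Markers of the remaining kidney cell types did not differ from matched lists in both libraries. Podocyte genes, of the glomerular filter, had 0.915 ± 0.441 distal regions per 10 kb, with Foxc2 at 3.08 ± 1.87, Synpo at 2.44 ± 0.328 and Wt1 at 0.0745 ± 0.105. In replicate 1 the podocyte list, at 1.23, lay above its upper random bound of 1.05 (adjusted permutation p = 0.0570), and in replicate 2 it had 0.603. Stroma, smooth muscle and renin cell genes had 0.779 ± 0.0124 (Col1a1 1.77 ± 0.576, Foxd1 1.40 ± 0.282, Akr1b7 0 in both libraries) and immune genes 0.757 ± 0.0611 (Cd74 1.56 ± 0.245, Cd79a 1.21 ± 0, Adgre1 0 in both). Distal convoluted tubule genes had 0.688 ± 0.00921, with Emx1 at 2.70 ± 0.382 and the sodium chloride cotransporter gene Slc12a3 at 2.37 ± 0.620, against Calb1 at 0.214 ± 0. Principal cells of the collecting duct had 0.654 ± 0.0298, where the sodium channel subunit genes Scnn1a and Scnn1g had 2.03 ± 0.319 and 0.185 ± 0, and Hsd11b2 had 1.59 ± 0.560. Intercalated cells, which secrete acid or base, had 0.515 ± 0.132, with Slc4a1 at 1.87 ± 0.378, Hmx2 at 1.71 ± 1.93 and Oxgr1 at 0.233 ± 0.

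Lists of other tissues and states also stayed within their random lists. For those with a lower random bound of 0, only a higher density could have been called. Adipocyte genes had 1.09 ± 0.278 distal regions per 10 kb (Fabp4 1.84 ± 0.289, Plin1 1.38 ± 0.216, Ucp1 0.356 ± 0), housekeeping genes 0.752 ± 0.0498 (Actb 3.17 ± 0.299, Rps18 0 in both libraries) and urothelium 0.730 ± 0.0812 (Upk1a 2.02 ± 0, Krt15 0.827 ± 0, Krt5 0.387 ± 0). Adrenal cortex had 0.520 ± 0.257 (Nr5a1 1.43 ± 0, Cyp21a1 0.862 ± 0.609, Cyp11b1 0 in both), germ cells 0.490 ± 0.00352 (Tnp2 1.45 ± 0, Prm2 1.21 ± 0, Pgk2 0 in both) and striated muscle 0.467 ± 0.0340 (Myog 1.99 ± 0.313, Nppa 1.17 ± 0.331, Myh1 0 in both). Neuron genes had 0.376 ± 0.0629 (Slc17a7 1.55 ± 0.439, Camk2a 1.39 ± 0.428), erythroid genes 0.359 ± 0.0133 (Tal1 1.70 ± 0, Epor 1.63 ± 0.575, Hba-a1 0 in both) and hepatocyte genes 0.340 ± 0.00743. The hepatocyte genes Fgg and Apoa1 had 2.20 ± 0.518 and 1.83 ± 0, and Cyp3a11 had 0 in both. Nephron progenitor genes had 0.714 ± 0.166 (Sall1 3.52 ± 2.30, Meox1 2.03 ± 0.192, Eya1 0.279 ± 0.132). Genes with higher tubule expression in males had 0.465 ± 0.152 (Nudt19 2.40 ± 0.486, Kap 2.09 ± 0, Cyp7b1 0.104 ± 0.0739) and those higher in females 0.564 ± 0.0795 (Cyp2a4 0.895 ± 0.253, Abcc3 0.789 ± 0.101, Slc22a29 0.127 ± 0.180).

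Transcription factor genes of other lineages varied most between the libraries, at 1.12 distal regions per 10 kb in replicate 1 and 0.407 in replicate 2. Neurog2, a neuronal determination gene, had 15 and 2 distal regions, Gsc had 8 and 1, and Isl1 had none in either library. Their promoters were accessible in 11 of 16 genes in replicate 1 and in 5 of 16 in replicate 2. The median promoter signal of the list was only 0.226, with genes lacking a promoter region counted as 0. The median protein-coding gene had 0.573 distal regions per 10 kb in replicate 1 and 0.457 in replicate 2. Replicate 1 had the greater inferred depth, and depth, instrument and animal cannot be separated here.

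Every housekeeping gene had an accessible promoter in both libraries (15 of 15), above matched lists with an adjusted permutation p of 0.023 in replicate 1 and 0.00613 in replicate 2. Only 1 of 14 hepatocyte genes had one (7.14% in each library, adjusted permutation p = 0.0046 in each), and genes such as Alb, Ttr and Cyp7a1 had none. The other 21 lists did not pass in both libraries, and 5 of 23 lists had an unadjusted p under the threshold in both. Promoter shares were high in endothelial (100% ± 0, SD, n = 2), distal convoluted tubule (95.8% ± 5.89), principal cell (95.8% ± 5.89), kidney transcription factor (95.7% ± 0), proximal tubule (94% ± 2.83) and thick ascending limb genes (93.3% ± 0). They were intermediate in male-biased tubule (87.5% ± 0), stromal (85.7% ± 0), podocyte (84.6% ± 10.9), nephron progenitor (75% ± 21.2), intercalated cell (73.1% ± 5.44), female-biased tubule (66.7% ± 23.6), neuron (60.7% ± 5.05) and other-lineage transcription factor genes (50% ± 26.5). Low shares were those of adipocyte (42.9% ± 0), immune (36.7% ± 4.71), erythroid (29.2% ± 5.89), germ cell (25% ± 0), adrenal cortex (25% ± 0), urothelium (21.4% ± 10.1) and striated muscle genes (21.4% ± 10.1). In the larger deposited peak set neither the housekeeping call (100%) nor the hepatocyte call (21.4%) was kept.

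**Figure D1:**
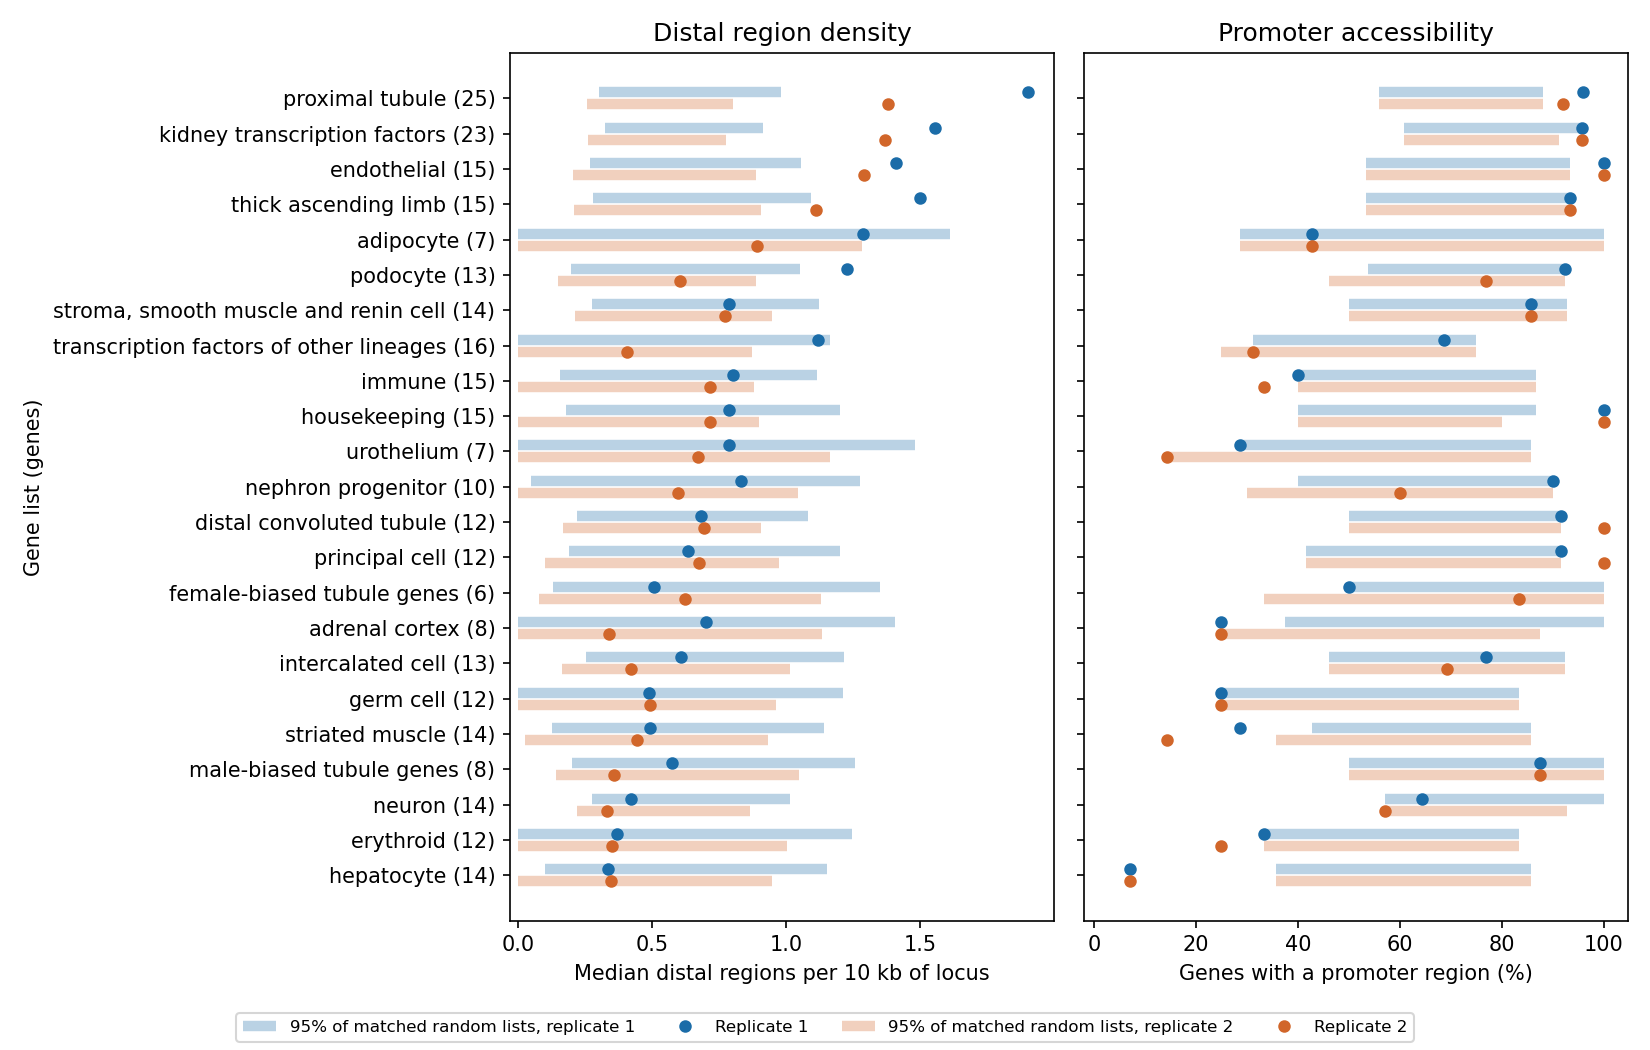
Left: median distal regions per 10 kb of locus for each gene list; right: percent of its genes with an accessible promoter. Points are the 2 libraries and bars span 95% of matched random lists; proximal tubule lies at 1.90 and 1.38 and hepatocyte promoters at 7.14%.

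Among single loci, the largest numbers of distal regions stood in long genes. The annotated gene Gm20388, a locus of 4455 kb that runs across several neighbours on chromosome 8, held 584.5 ± 99.7 distal regions (SD, n = 2). The annotated locus of Fgfr2, of 2981 kb on chromosome 7, also spans other genes, among them Hmx2, and held 246.5 ± 31.8. Tns1 held 94.5 ± 27.6, Syn3 93.5 ± 27.6 and Gse1 93 ± 15.6. Pde4d held 91.5 ± 2.12, Gm37240 83 ± 9.90, Lrmda 80.5 ± 2.12, Camta1 78 ± 7.07 and Nav2 77 ± 2.83. Relative to length, only Tns1 among these 10 loci (chromosome 1, 73910231 to 74124449), which encodes the focal adhesion protein tensin, had more than 4 per 10 kb (4.03 ± 1.18).

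Regions found in 1 library alone were mostly weak. Replicate 1 had 40248 of them and replicate 2 had 18218, with a median signal of 0.464 and 0.554 against 1.43 for shared regions in either library. Promoters made up 12.7% and 10.96% of them. The strongest of replicate 1 lay at the promoters of Atf2 (signal 21.7), Rbpj (16.6), Nup98 (15.3) and Gtpbp1 (14.99), and near Fbrs (14.9). Those of replicate 2 lay near Khsrp (18.6), Prrc2a (13.6) and Anp32e (11.1) and at the promoters of Fem1c (16.0) and Ap1m1 (13.0). All 10 lay within 120 bp of a region of the other library, and 100% of their bases were listed in its false discovery rate file. Of the single-library regions, 60.6% in replicate 1 and 77.2% in replicate 2 had a base listed in the other library, and 50% and 58.3% overlapped its larger peak set. Their number reached 104706 over both libraries in the larger peak set.

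Footprints, short protected stretches inside accessible chromatin where a bound protein shields DNA, numbered 614314 in replicate 1 and 396123 in replicate 2. Their median widths were 12 and 11 bp. Inside the accessible regions lay 71.3% and 78.3% of them (mean 74.8% ± 4.94, SD, n = 2), and the strongest quartile of regions held 4.17 and 3.96 footprints per region against 1.63 and 1.19 in the weakest quartile. Of the footprints inside regions, 51.5% in replicate 1 and 75.1% in replicate 2 overlapped a footprint of the other library, against 39.7% and 52.9% after random moves within the same region. When an overlap of 50% of both footprints was required, 43.6% ± 10.4 were shared, compared with 63.3% ± 16.7 for an overlap of 1 bp.

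Footprints in mouse kidney carried the motifs of CTCF, the insulator protein, of the repressor REST and of the NFI family far more often than other sequence in the same regions. The NFI consensus occurred in 181 and 136 footprint windows and in no control window, at least 60.3-fold and 45.3-fold higher against a floor of 3 counts per library. REST occurred in 125 and 163 footprint windows and in 1 control window each, ratios of 125 (95% exact interval 22.0 to 4976) and 163 (28.8 to 6477). CTCF was 40.1-fold and 67.9-fold enriched (mean log2 fold 5.71 ± 0.54, SD, n = 2). The higher fold in replicate 2 does not mean that more CTCF sites were footprinted there. Of 9396 CTCF matches in shared regions, 9066 counted as footprinted in replicate 1 and 8353 in replicate 2. The DR1 element bound by PPAR and RXR occurred in 26 and 21 footprint windows and in no control, at least 8.67-fold and 7-fold higher, and CREB/ATF was 19.9-fold and 16.2-fold enriched. HNF4, a nuclear receptor of the proximal tubule and liver, was enriched 3.89-fold and 7.60-fold.

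Of 26 motifs, 17 were enriched and 3 depleted in both libraries by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment. The depleted ones were FOX (0.350-fold and 0.298-fold), GATA (0.484 and 0.511) and POU (0.595 and 0.633). The other 6 did not pass in the same direction in both libraries, which does not make them alike in the 2 libraries. Footprint windows were richer in GC than control windows (58.0% and 57.6% against 53.3% and 53.5%), and with both thinned POU was no longer called (log2 fold -0.15) and TEAD was (0.16). The call for NFY was lost without widening the footprints (log2 fold 0.29).

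**Figure D2:**
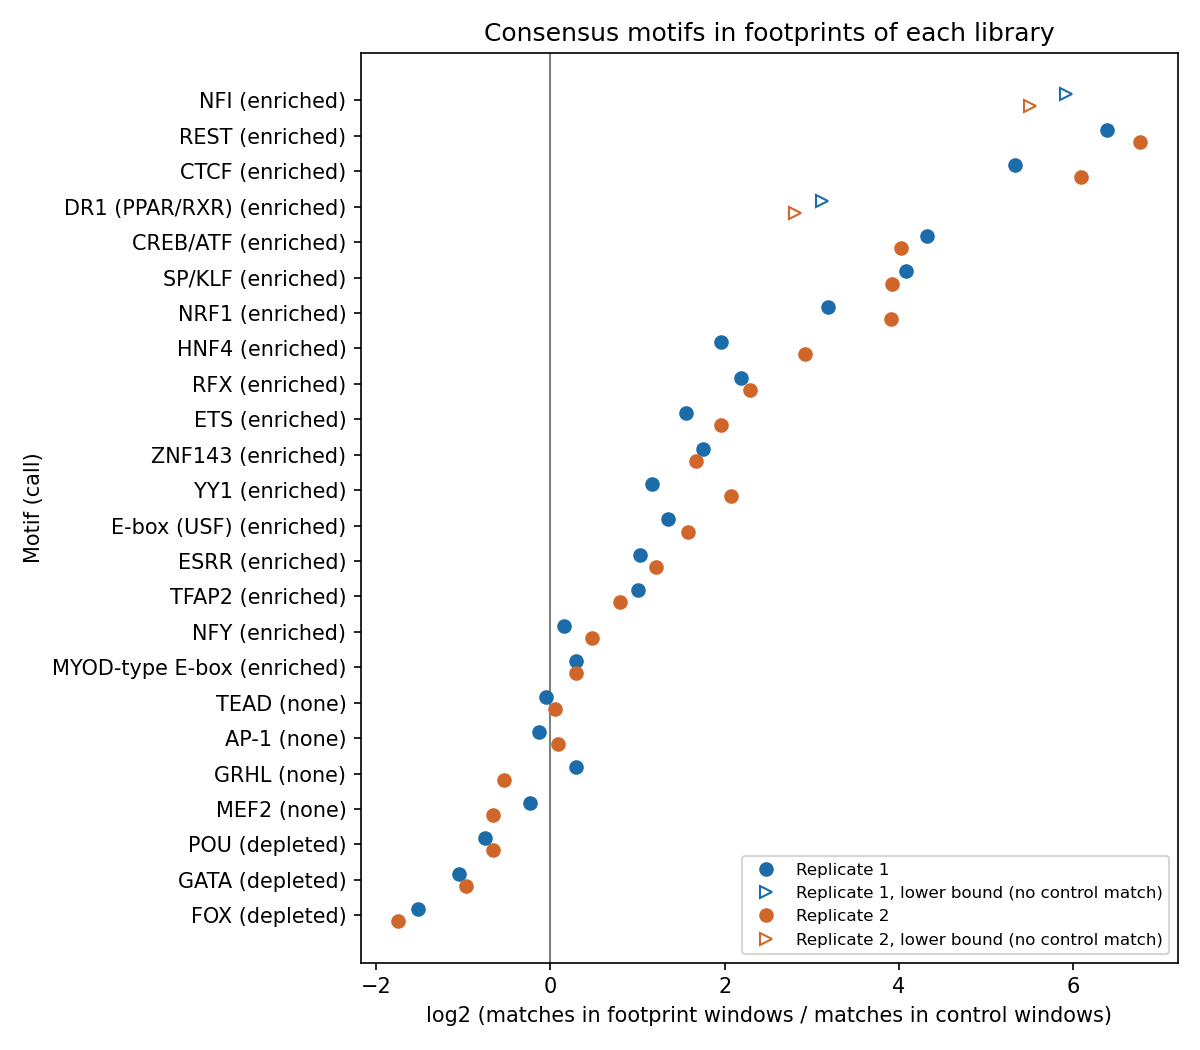
Log2 ratio of motif matches in footprint windows to matches in control windows of the same regions, for the motifs reported; points are the 2 libraries and open triangles are lower bounds where no control window matched. CTCF lies at 5.33 and 6.08 and FOX at -1.51 and -1.75.

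Distal and promoter footprint windows carried different motifs. Their shares were compared directly, without control windows for either kind and without matching on GC content. Such a difference can reflect how often a consensus occurs in each kind of sequence, so it does not measure binding. Only footprints with a control window were used, so the shares do not compare the libraries either. CTCF was more frequent in distal windows by 2.53 ± 0.09 on the log2 scale (SD, n = 2), NFI by 2.11 ± 0.05, HNF4 by 1.76 ± 0.04 and ESRR by 1.62 ± 0.23. Promoter windows held more YY1 (log2 distal over promoter -5.05 ± 0.42), ZNF143 (-4.50 ± 0.10), NRF1 (-3.72 ± 0.27), ETS (-3.07 ± 0.23), SP/KLF (-2.68 ± 0.36) and NFY (-2.02 ± 0.24). The ratios of YY1 and ZNF143 rest on very few distal matches. YY1 stood in 0.00347% and 0.00341% of the 259639 and 205030 distal windows, and ZNF143 in 0.00116% and 0.00146%. The SD between the libraries does not cover this counting error. The CTCF consensus, for example, stood in 1.37% of distal and 0.226% of promoter windows in replicate 1, and in 2.62% and 0.475% in replicate 2. Each of these differences was larger than its spread between the libraries and had the same sign in both; no test was made across animals.

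**Figure D3:**
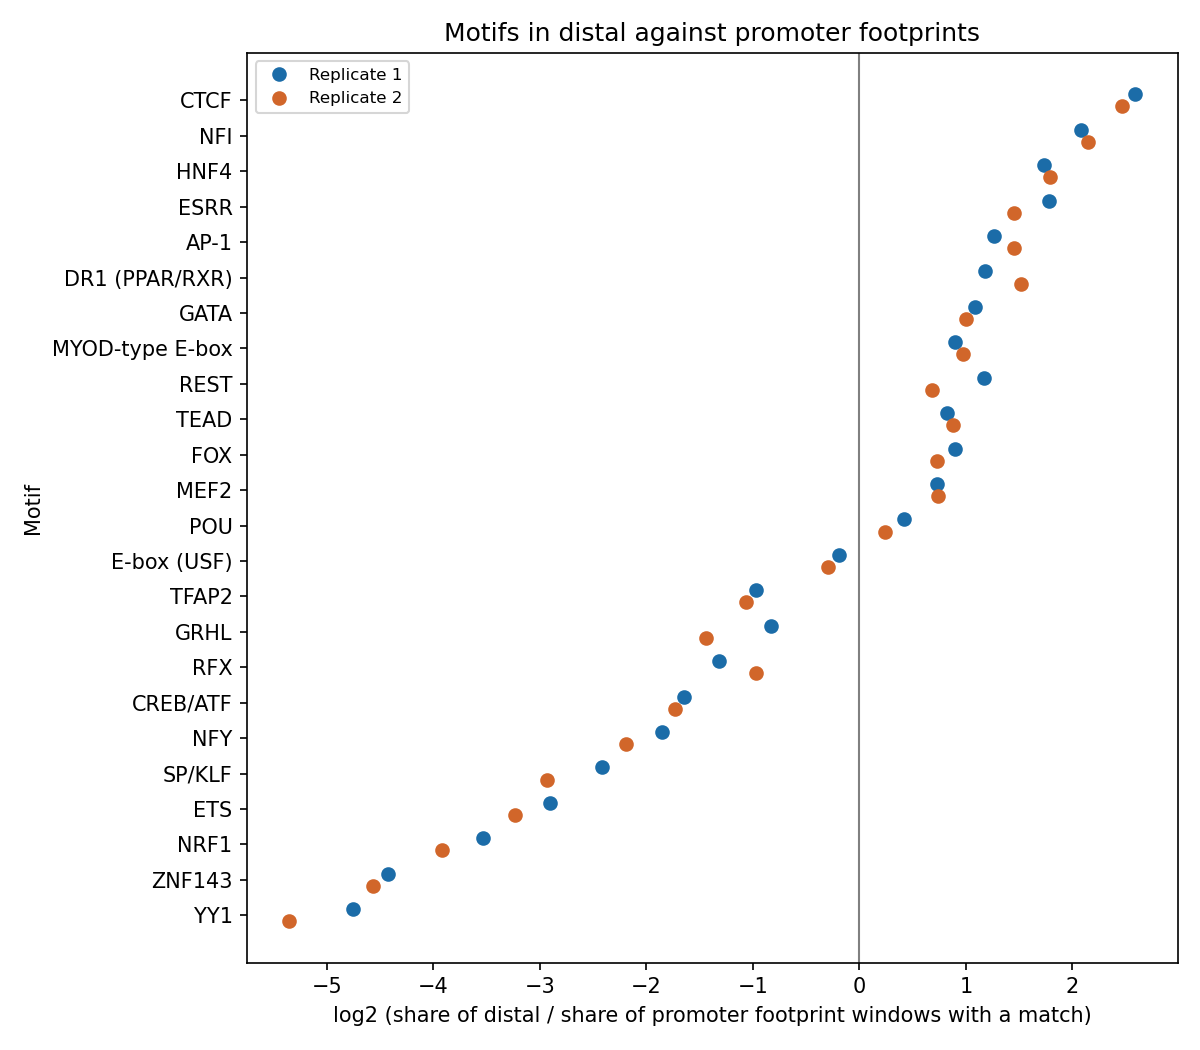
Log2 ratio of the share of distal to the share of promoter footprint windows with each motif; points are the 2 libraries. CTCF lies at 2.59 and 2.46 and YY1 at -4.75 and -5.35.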

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

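The tests of CTCF regions were chosen only after the result was seen; the other tests were set down after their pattern appeared and before they were run.

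Signal was also present outside the peak sets used. Bases listed in the false discovery rate files but outside the larger peak set came to 30.3 Mb in replicate 1 and 25.01 Mb in replicate 2, which is 42.2% and 42.3% of all listed bases. Of these, 70.6% of the replicate 1 bases were listed in replicate 2 too, and 87.3% of the replicate 2 bases in replicate 1. Sequences in this part were not analysed here.

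Replicate 1 had 40248 regions without a partner in replicate 2, and the strongest of them lay beside a replicate 2 region. A difference in depth, with the region in replicate 2 falling below its threshold, is a candidate explanation. Of these regions, 60.6% had a listed base or a larger-set region in replicate 2 (95% exact interval 60.1 to 61.0). The reverse share was higher: 77.2% of the regions of replicate 2 alone had one in replicate 1, whose inferred depth was greater. Any disagreement near a threshold can give such a share, so it does not single out depth. The remaining 15877 regions of replicate 1 alone had neither, and depth and animal cannot be separated for them. Of all 40248 regions, 24.9% lay within 500 bp of a called replicate 2 region, and of the strongest 1% of them 71.5% did. For these, a listed base or larger-set region may belong to that neighbour, so it does not show a region below the threshold.

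Shared regions around 5 of 23 gene lists were not equally strong in the 2 libraries. With the GC and strength trend removed, proximal tubule (log2 replicate 1 over replicate 2 of -0.19) and endothelial lists (-0.19) leaned to replicate 2. Neuron (0.49), striated muscle (0.59) and other-lineage transcription factor lists (0.51) leaned to replicate 1. Their matched random lists had medians of 0.086 to 0.101, and the shifts were tested against these. A trend with GC content and strength is argued against as the whole cause, since 5 of the 6 lists shifted before it was removed kept an adjusted p under the threshold by permutation, and CTCF regions stayed at 0.95. A different make-up of the tissue pieces may account for part of it. With the trend removed, 2 of 9 kidney marker lists passed the threshold towards replicate 2 and 0 towards replicate 1. Of the kidney lists that did not pass, distal convoluted tubule lay below its random median (-0.016 against 0.083). The others lay above theirs, up to 0.32 against 0.091 for principal cell. A different make-up cannot be told apart from a difference between the libraries as long as each animal has 1 library. Before the trend was removed, regions with motifs of widely used promoters shifted by at most 0.21 and CTCF regions by 1.11, but such promoters would stay put under a different make-up too, so this leaves it open for CTCF. Digestion or fragment selection, which could act on CTCF and REST sites, was not tested. A biological difference between the animals cannot be told apart from one between the libraries. Tests that bear on it are among the results not reported here.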

How the results depend on the processing

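The thinning to equal GC content was chosen after the data were seen; the other settings were fixed beforehand, and 20 of 62 values of the main results moved further than the limit for their kind (the SD between libraries, a ratio for counts, an interval for the correlation). Leaving out either of 2 libraries cannot move a mean beyond that SD, so it tests no mean here. The region count was 71672 with the stronger regions of each library by construction. The signal rank correlation, 0.857, was 0.879 with the larger peak set, 0.838 with equal numbers and 0.855 with reciprocal overlap. The promoter share was 16.2%, 30.9% and 21.8% with the larger set, stronger regions and equal numbers, and 27.2% with a window of 1000 bp. Genes with an accessible promoter came to 71.8% with the larger set and 61.4% with stronger regions. Lists with promoters above matched lists numbered 0 with the larger set and 2 with stronger regions, against 1. Single-library regions numbered 104706 with the larger set and 25377 with stronger regions, against 58466. Footprints inside regions were 87.6% and 49.9% with the same settings, and footprints shared were 43.6% with reciprocal overlap. Density on X relative to autosomes was 0.375, 0.231 and 0.304 with the larger set, stronger regions and equal numbers. The cause was not tested. The lists above for distal density numbered 3 to 4 and motifs enriched 17 to 19 over their settings. Of the lists with no promoter call, 4 passed in at least 1 setting (6 cases), for example striated muscle as lower without replicate 1 (14.3%). The alternative that uses the stronger footprints was not run, since their value is constant. No paired analysis was possible because there is 1 group.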

Other observations

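The tests of HNF4 and CTCF sites by gene list and the repeat on percentiles were chosen only after the result was seen.

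CTCF sites footprinted in both libraries were not enriched in any of the 23 lists (adjusted permutation p = 1 throughout), and HNF4 sites in none after the correction. Only 565 HNF4 sites were footprinted in both, so enrichment can be missed. They stood at 17.4% of kidney transcription factor genes against 3.40% in random lists (unadjusted permutation p = 0.0134, adjusted 0.308). For proximal tubule genes it was 12% against 2.62% (unadjusted 0.0540, adjusted 0.621). Podocyte and erythroid lists had 1 gene each, and the other lists none.

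On the percentile scale, CTCF regions ranked 16.4 points higher in replicate 1 and REST regions 27.2 points higher, and HNF4 regions lower (-6.00). The lists with a shift on either scale kept its direction, with male-biased tubule genes at -4.40 (adjusted permutation p = 0.0445, against 0.139 on the log2 scale), proximal tubule at -4.89, endothelial at -4.81, striated muscle at 14.5, neuron at 9.76 and other-lineage transcription factors at 9.42. Matched random lists of these had medians of 1.43 to 1.63 points. In 90.2% of CTCF regions and 98.5% of REST regions the trend-corrected ratio favoured replicate 1.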
